A study of Mus musculus with 41 samples.

How the data were processed

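Chromatin immunoprecipitation followed by sequencing had been run on chondrocytes sorted by flow cytometry from embryonic mouse cartilage. Proliferating chondrocytes (PC) came from embryonic day 13.5 and carried a Col2a1-driven Cre transgene with a YFP reporter in the Rosa26 locus. Hypertrophic chondrocytes (HC) came from embryonic day 15.5 and carried a Col10a1-driven Cre transgene with the same reporter, so cell type, age and strain changed together. Low-input immunoprecipitation and library kits were used, per the labels' protocols. Of the 41 samples, 30 had a region list, with 3 PC and 2 HC libraries for each of 6 histone modifications, H3K4me3, H3K9ac, H3K27ac, H3K27me3, H3K36me3 and H3K9me3. The series' design text speaks of 5 modifications, whereas the labels give 6. The other 11 samples were IgG controls, 7 from PC and 4 from HC, and were not analysed here. Libraries are named by cell type and the number in the sample title. The labels do not say whether libraries of 1 group came from separate litters or from 1 pool, so p-values measure only the spread between these libraries, which may be technical.

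The authors deposited 1 list of region coordinates per library and 1 intersected list per mark and cell type. Each list gives a chromosome, a start and an end with no score, height or read count, so the sequencing depth behind a region is unknown. Region edges fell on a grid of 200 bp for H3K4me3, H3K9ac and H3K27ac and of 800 bp for H3K27me3, H3K36me3 and H3K9me3. The submitters' processing notes name FastQC, Picard and the mouse build mm10. The aligner and the region caller, and whether IgG entered the calling, are not given in the sources used here. How much was called differed between lists of 1 mark, from 46.1 to 98.4 Mb for H3K27ac, and a longer list marks more genes.

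Genes were 21887 protein-coding entries of the RefSeq table for GRCm38.p6, the same assembly as mm10. The table gives no strand. The promoter was therefore taken as the gene end, with 2 kb on each side, that carried H3K4me3 in at least 1 library. For 11398 genes this picked 1 end. Both ends were used for the other 10489, of which 7045 carried H3K4me3 at neither end and 3444 at both. This departs from the planned use of the 5 prime end. For H3K4me3, H3K9ac, H3K27ac and H3K27me3 a promoter was marked when at least 200 bp of its window lay in regions. For H3K36me3 and H3K9me3 a gene was marked when at least 25% of its body lay in regions.

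Comparisons within each mark set 3 PC libraries against 2 HC libraries. Region number, covered length and the Jaccard index (shared over combined base pairs) were compared by exact permutation over the 10 splits of 5 libraries into 3 and 2, which cannot go below p = 0.1. A gene was called PC-only when marked in all 3 PC and neither HC library, and HC-only when marked in both HC and no PC library. These counts carry no p-value and stand beside the highest count from the 9 other splits. Covered percent per gene was tested with limma (moderated linear model with trend and robust settings) among genes covered in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05. Gene lists for cell types and pathways were fixed before the data were examined. They covered cartilage matrix and early chondrocyte genes, hypertrophic chondrocyte, osteoblast and osteocyte, cell cycle, cyclin-dependent kinase inhibitors, Hox genes, Hedgehog and PTHrP, BMP and TGF-beta, Wnt, hypoxia and glycolysis, perichondrium with tendon and joint, muscle, endothelium, blood cells, osteoclast, neural, epidermis, other-lineage transcription factors, housekeeping, zinc finger genes, olfactory receptors and histones, the last chosen by gene name with variants included. Each list was compared with the other genes marked in at least 2 libraries by a two-sided Fisher's exact test, adjusted over 264 tests. Genes are not replicates, so these p-values describe these libraries. Genes marked in all 5 libraries stay in the background although they cannot be called. A list of weakly marked genes can therefore pass more readily. Promoters were also sorted by presence of H3K4me3 and H3K27me3 in every library of a cell type. H3K27ac regions over 2 kb from any gene end were given to the nearest gene within 100 kb.

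Named genes followed a rule fixed before the data were examined. It took members of the cartilage, hypertrophic and Hox lists with a call, and 7 genes in any case (Col2a1, Acan, Sox9, Col10a1, Runx2, Ihh and Mmp13). It added the 5 genes per mark and direction with the greatest difference, and members of lists with a significant test. Members of other lists that passed within their own list were named after their values were seen. So were the genes with distal regions. Not every gene that the rule took is named.

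The interval, permutation and list functions were tested on simulated data, with 0 errors in 4080 interval checks, 20 permutation p-values and 600 planted genes. The limma step was tested on real gene means with resampled residuals and 200 genes shifted in HC. There were 4 simulation designs, each changed after its recovery had been seen, and recovery depended on the design. The design tried last, with permuted residuals of any gene, was kept after its recovery had been seen, so that recovery is not an independent measure. In this design shifts of 80 percentage points were called in 97% of planted genes for H3K4me3, 92% for H3K9ac and 83% for H3K27ac. They were called in 51% for H3K27me3, 62% for H3K36me3 and 89% for H3K9me3. Shifts of 40 points were called in 57%, 21%, 15%, 2%, 1% and 63%. False calls were 10 of 164, 1 of 114, 3 of 101, 5 of 58, 6 of 69 and 34 of 186. With permuted residuals of a gene of like mean, 0% of shifted H3K27me3 and H3K9me3 genes were called at either size. With residuals pooled over genes of like mean, 0% were called for H3K27me3, H3K36me3 and H3K9me3. Bootstrap draws from a gene of like mean also recovered genes in every mark, at 36% to 96%. They gave 39 to 79 false calls per mark, such as 41 of 196 calls for H3K4me3 and 75 of 202 for H3K27me3. A low number of limma calls thus says little about how many genes differ, and in the kept design the share of false calls exceeded 5% for H3K4me3, H3K27me3, H3K36me3 and H3K9me3.

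Alternatives fixed in advance were lists trimmed from the narrowest region to equal covered length, the wider regions of each list alone, merging of nearby regions, other windows and minimum overlaps, log2(percent + 1), all genes covered in any library, other backgrounds, a replicate block for H3K9ac, and leaving out each library. With no scores in the lists, trimming removes narrow regions from the longer lists only. Added after seeing the data were both gene ends for every gene, single-bin regions left out, transgene loci left out, autosomal genes only, and equal autosomal covered length. The transgene loci were Mt1, Mt2, Prm1 and the genes around Col2a1 and Col10a1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.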

Results

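Regions of 6 histone modifications were mapped in chondrocytes, the cells of cartilage, sorted from embryonic mice. The comparison addressed how chromatin differs between proliferating chondrocytes (PC) and hypertrophic chondrocytes (HC), the enlarged cells they become in the growth plate. Each mark had 3 PC libraries from embryos at E13.5 and 2 HC libraries from embryos at E15.5, 30 libraries in all. The PC mice carried a Col2a1-driven Cre transgene and the HC mice a Col10a1-driven one, so cell type, age and strain differed together. H3K4me3, H3K9ac and H3K27ac lie at active promoters, H3K27ac also at enhancers, H3K36me3 along transcribed genes, H3K27me3 at Polycomb-repressed genes and H3K9me3 in heterochromatin. The read depth behind the lists is unknown. The lists held 20133 to 33355 regions per library for H3K4me3, 24196 to 51666 for H3K9ac and 51645 to 105752 for H3K27ac. They held 17842 to 26980 regions for H3K27me3, 68411 to 192688 for H3K36me3 and 47125 to 155011 for H3K9me3. Gene values are the percent of the promoter window, or of the gene body for H3K36me3 and H3K9me3, that lay in regions, as mean ± SD with n = 3 for PC and n = 2 for HC. Positions are in mm10.

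Most regions of the active promoter marks were common to both cell types. Of the regions in the PC group list, 93.0% overlapped the HC list for H3K4me3 and 85.7% for H3K9ac, and 91.7% and 84.3% of HC regions overlapped the PC list. For H3K27ac the shares were 60% of PC and 69.0% of HC regions, for H3K36me3 63.1% and 75.5%, and for H3K9me3 44.2% and 41.3%. For H3K27me3, 80% of PC regions but 54.6% of HC regions overlapped, with group lists of 35.9 Mb in PC and 75.5 Mb in HC. A PC group list intersects 3 libraries and an HC group list 2, which by itself shortens the PC list. For H3K27me3, rebuilt intersections covered 34.2 Mb from 3 PC libraries, 38.3 to 45.0 Mb from 2, and 67.3 Mb from the 2 HC libraries. Region number was 40340 ± 10728 in PC and 24877 ± 963 in HC for H3K9ac, and 29623 ± 3909 and 21775 ± 2321 for H3K4me3 (two-sided exact permutation p = 0.2 each, adjusted p = 0.36). It was 86231 ± 19757 and 63236 ± 16392 for H3K27ac, 144070 ± 63622 and 83255 ± 20992 for H3K36me3, and 108538 ± 40797 and 62261 ± 21406 for H3K9me3. For H3K27me3 it was 22882 ± 4641 and 21272 ± 3586, and the exact permutation p-values of these last marks were 0.2 to 0.7. Covered length was 74.9 ± 15.6 Mb in PC and 98.5 ± 0.653 Mb in HC for H3K27me3, and higher in mean in PC for the other 5 marks (exact permutation p = 0.2 to 0.7). Without HC replicate 5 it was higher in HC, by 6.87 Mb for H3K27ac and 19.3 Mb for H3K9me3. The mean Jaccard index for H3K27ac was 0.447 within PC, 0.365 within HC and 0.357 between cell types (one-sided exact permutation p = 0.1, adjusted p = 0.4). HC replicate 7 shared more with each PC library (0.369 to 0.409) than with HC replicate 5 (0.365). The index was 0.648, 0.745 and 0.689 for H3K4me3 (exact permutation p = 0.7), and the other marks had p = 0.2 to 0.4. No split of 3 and 2 libraries can give p under 0.1.

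Several genes of the cartilage matrix and of early chondrocytes carried less active chromatin in HC. H3K27ac at the promoter of Col9a1, a chain of type IX collagen (chromosome 1, 24177589 to 24252738), fell from 93.2% ± 3.06 in PC to 0% in HC (difference -93.2, SE 6.13, limma adjusted p = 0.0291). At Matn1, which encodes the matrix protein matrilin 1 (chromosome 4, 130944385 to 130955476), it fell from 93.3% ± 7.64 to 0% (difference -93.3, SE 7.04, adjusted p = 0.0396). These were the only H3K27ac calls among 14165 genes, with 393 genes higher and 832 lower at an unadjusted p under 0.05. Both calls were lost at equal covered length, on the log2 scale, and without PC replicate 3, PC replicate 5, HC replicate 5 or HC replicate 7, each of which left 0 calls. Of 28 cartilage list members tested for H3K27ac, 14 fell and 1 rose when adjusted over the list alone, against 2 and 0 over all genes. The members that fell included Sox9, the master regulator of chondrocytes (93.0% ± 2.50 to 59.3% ± 12.4), Col11a2, a type XI collagen chain (96.7% ± 5.77 to 48.0% ± 7.07), Chad, which encodes chondroadherin (63.4% ± 9.01 to 10% ± 14.1), and Ucma, a cartilage matrix protein (57.0% ± 18.2 to 5.00% ± 7.07). The count was 9 at equal covered length. The gene for aggrecan, Acan, had 82.3% ± 7.64 in PC and 67.5% ± 3.54 in HC (limma adjusted p = 0.622 over all genes).

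Other marks of activity on the cartilage list pointed the same way. For H3K9ac, 13 of 27 members fell and 1 rose adjusted over the list alone, against 0 and 1 over all genes. They included Hapln1, a link protein of the matrix (98.3% ± 2.89 to 64.1% ± 27), Sox9 (68.0% ± 7.5 to 40.4% ± 3.92) and Acan (75.6% ± 0 to 57.5% ± 3.54). Without HC replicate 3, and with a replicate block, 3 members fell. In the same HC libraries 8 of 14 epidermis and 4 of 10 muscle members rose for H3K9ac, and 5 of 15 epidermis members for H3K27ac, adjusted over their lists alone. For H3K36me3 along the gene body, 12 of 27 members fell and 0 rose adjusted over the list alone, against 0 over all genes. Acan fell from 89.5% ± 7.58 to 42.7% ± 5.49 and Hapln1 from 83.2% ± 9.67 to 15.1% ± 2.38, and without HC replicate 5 the count was 4. For H3K4me3, 5 of 28 members fell and 1 rose adjusted over the list alone, against 0 and 1 over all genes. Those that fell were Col9a1, Cytl1, Matn1, Snorc and Sox9, and at equal covered length 2 fell and 1 rose. The H3K4me3 count was 16 without PC replicate 7, 12 without HC replicate 2 and 3 without HC replicate 5. By the rule of presence in every library of 1 cell type and no other, Matn1, Hapln1, Susd5 and Pthlh, which encodes a hormone that delays hypertrophy, were PC-only for H3K36me3. This was 4 of 26 members (Fisher's exact adjusted p = 0.0469), and without PC replicate 4 the 4 members gave an adjusted p of 0.2. For the other active marks the test did not pass, with 2 of 28 PC-only for H3K27ac (adjusted p = 0.4), 3 of 27 for H3K9ac (0.0566) and 0 of 28 for H3K4me3 (1).

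**Figure D1:**
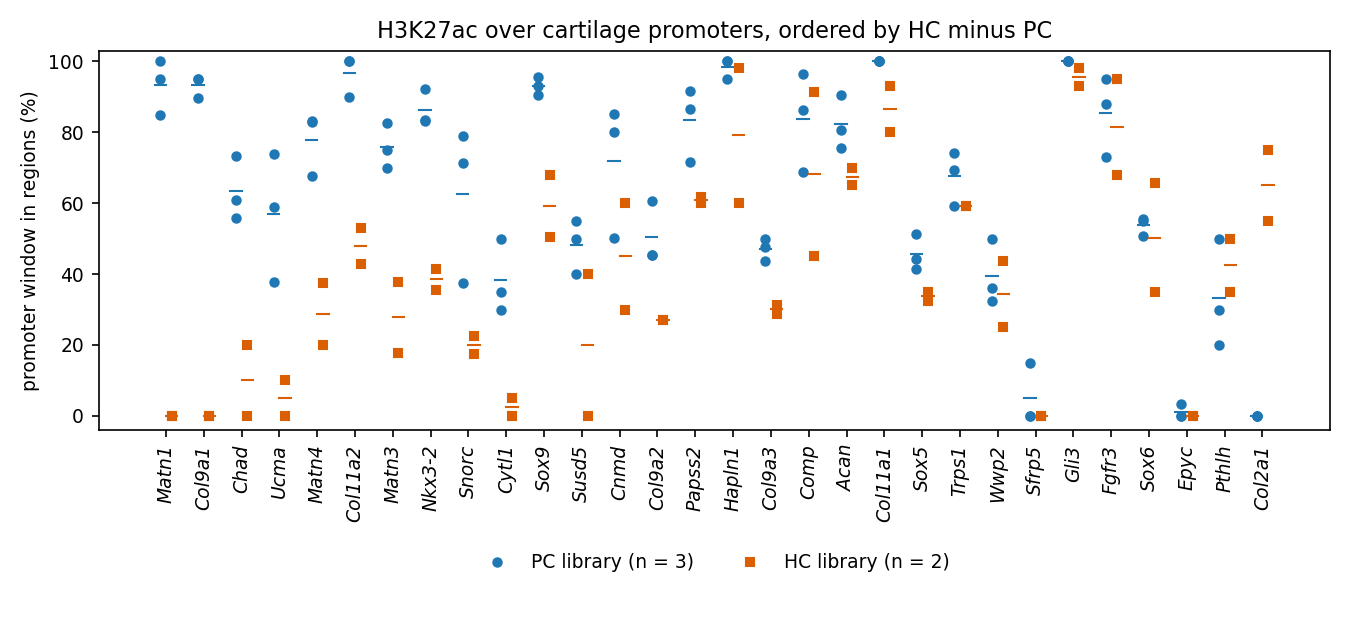
Percent of the promoter window in H3K27ac regions for members of the cartilage list, with 1 point per library for 3 PC (blue) and 2 HC (orange) libraries and short lines at the means. Col9a1 and Matn1 sit at 0% in both HC libraries, and Col2a1 at 0% in the PC libraries.

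The member that rose was Col2a1, the type II collagen gene (chromosome 15, 97975602 to 98004724), whose promoter sequence also drives Cre in the PC strain. Its H3K4me3 rose from 8.33% ± 2.89 to 79.4% ± 3.54 (difference 71.1, SE 5.09, limma adjusted p = 0.00266) and its H3K9ac from 0% to 71.9% ± 0 (difference 71.9, SE 4.86, adjusted p = 0.0153). Its H3K27ac was 0% in PC and 65.0% ± 14.1 in HC (adjusted p = 0.152 over all genes). H3K27me3 covered 100% of its promoter window in both cell types, and H3K36me3 covered 79.2% ± 10.4 of the gene body in PC and 73.5% ± 8.74 in HC. Regions of the 3 active marks ended at position 98001200 in 9 of 9 PC libraries, followed by a gap. Short H3K4me3 regions lay in the gap at 98004201 in all 3 PC libraries, and H3K27ac resumed at 98007601. H3K27me3 and H3K9me3 regions over the promoter started at 98000801 in 6 of 6 PC libraries. Both HC H3K27me3 libraries had another start, and the HC H3K9me3 libraries had no region over the promoter. The PC values at this promoter may thus describe the transgene, and the rises need not be changes in the cells.

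**Figure D2:**
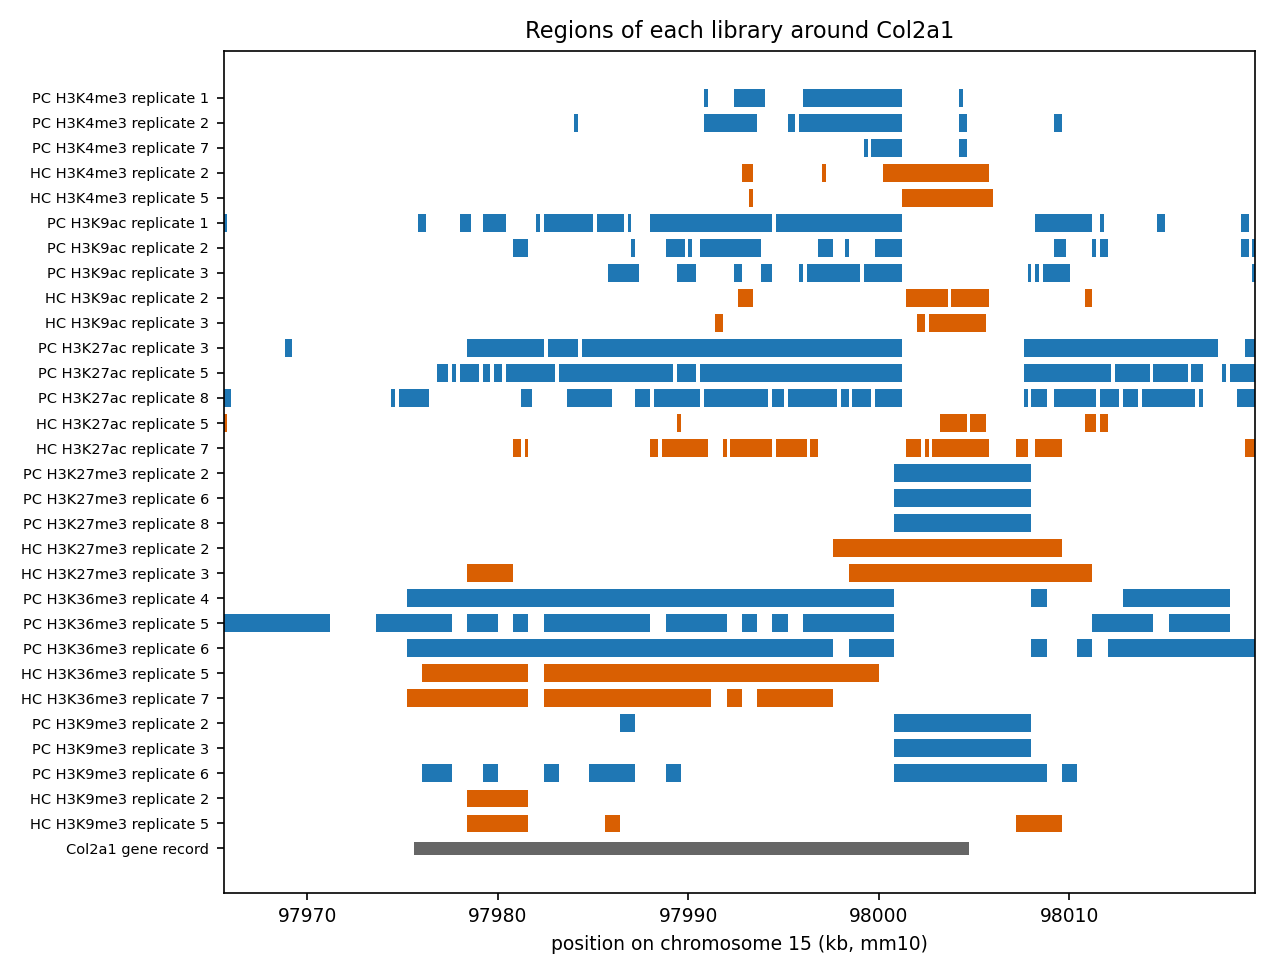
Regions of each library around the Col2a1 promoter on chromosome 15 (position in kb, mm10), with 1 line per library, PC in blue and HC in orange. In PC libraries the H3K27me3 and H3K9me3 regions share the start 98000801, and the active marks show a gap from 98001200 that holds short H3K4me3 regions at 98004201.

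The list of hypertrophic chondrocyte genes also carried less active chromatin in HC at most members that passed. For H3K9ac, 8 of 23 members fell and 1 rose adjusted over the list alone, against 0 and 0 over all genes. In the same HC libraries 8 of 14 epidermis and 4 of 10 muscle members rose for H3K9ac, and 5 of 15 epidermis members for H3K27ac, adjusted over their lists alone. Runx2, a transcription factor that drives hypertrophy (chromosome 17, 44495987 to 44814797), fell from 71.7% ± 20.2 to 0% for H3K9ac and from 66.7% ± 10.4 to 0% for H3K27ac (limma adjusted p = 0.251 and 0.152 over all genes). Its H3K4me3 was 70.1% ± 13.2 in PC and 37.5% ± 24.8 in HC. For H3K27ac, 4 of 24 members fell adjusted over the list alone, against 0 over all genes. They were Runx2, Pth1r, the receptor of parathyroid hormone-related protein (45.3% ± 12.7 to 0%), Panx3, a channel protein (37.8% ± 10 to 0.619% ± 0.875), and Ptch1, the Hedgehog receptor (81.8% ± 5.77 to 45.0% ± 7.07). For H3K36me3, 3 of 21 fell, Runx2, Runx3 and Foxa3, against 0 over all genes. Col10a1, the type X collagen gene (chromosome 10, 34389981 to 34397085), rose for H3K9ac from 0% to 14.3% ± 2.52 adjusted over the list alone, and for H3K27me3 from 0% to 51.3% ± 0.177 (adjusted p = 0.0266 over all genes). Its H3K36me3 was 36.5% ± 32.1 in PC and 83.1% ± 7.96 in HC and its H3K27ac 1.31% ± 2.27 and 18.9% ± 14.1 (limma adjusted p = 0.717 and 0.547 over all genes). Its H3K9me3 was 3.75% ± 6.5 in PC and 51.0% ± 0 in HC, and the HC strain carries a transgene with Col10a1 sequence. With any 1 library left out, 0 members rose for H3K9ac. Ihh, the Hedgehog ligand of prehypertrophic cells, had H3K4me3 of 17.5% ± 16.4 in PC and 0% in HC, and Mmp13, a collagenase of late hypertrophy, had 0% for all 6 marks. Runx2, Panx3 and Smpd3 were PC-only for H3K9ac, 3 of 22 members (Fisher's exact adjusted p = 0.0469). This was 1 member at equal covered length (adjusted p = 0.329), where 2 members fell for H3K9ac and 0 for H3K27ac and H3K36me3. The Fisher test did not pass for H3K27ac (3 of 24 PC-only, adjusted p = 0.0833), H3K36me3 (3 of 18, 0.0833) or H3K4me3 (0 of 21, 1). The H3K9ac count was 5 without PC replicate 1 or PC replicate 2, 3 without HC replicate 2 and 1 without HC replicate 3, and the H3K36me3 count was 1 without either HC replicate.

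H3K27me3 gave the greatest number of limma calls. Of 4430 promoters, 218 rose and 29 fell in HC. Ptch1 (chromosome 13, 63508328 to 63573460) rose from 0% to 100% ± 0 (difference 100, SE 6.19, adjusted p = 0.0105). Sox9 (chromosome 11, 112782210 to 112787757) rose from 0% to 93.0% ± 7.07 (SE 6.90, adjusted p = 0.0115) and Sp7, a transcription factor of osteoblasts (chromosome 15, 102356603 to 102367035), from 0% to 91.3% ± 1.79 (SE 6.26, adjusted p = 0.0115). Among the largest rises were those from 0% to 100% at Cdh11, a cadherin of mesenchymal cells, Col12a1, a collagen, Cacna1g, a calcium channel subunit, and the X-linked Aff2. The largest falls were to 0%, from 91.6% ± 10.4 at Syne3, 89.4% ± 4.07 at Myf6, a regulator of muscle genes, 86.7% ± 11.6 at Pqlc3, 86.1% ± 11.5 at Abca4 and 84.5% ± 7.77 at Smok2b. On the cartilage list 7 of 15 members rose and 1 fell adjusted over the list alone, against 3 and 0 over all genes. They were Sox9, Sox5, Sox6, Col9a2, Col9a3, Chad and Matn4, with Sox6, a partner of Sox9, at 17.3% ± 11.5 in PC and 85.3% ± 20.8 in HC. Papss2, which supplies sulphate donors for the matrix, fell from 59.4% ± 19.2 to 0%. At equal covered length 4 of 12 rose and 0 fell, and the count of 7 was 0 without either HC replicate, 3 without PC replicate 6 and 4 without PC replicate 2. Col10a1, Ptch1 and Sp7 were the 3 of 13 hypertrophic members that rose, both adjusted over the list alone and over all genes. On this list 3 rose and 1 fell at equal covered length, and 6 rose without PC replicate 2 or PC replicate 6, 5 without PC replicate 8, 1 without HC replicate 2 and 0 without HC replicate 3. Acan had 99.8% ± 0.361 in PC and 100% ± 0 in HC, Ihh 18.6% and 28.6%, and Runx2 0% in both.

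The direction of the H3K27me3 difference depended on how the lists were scaled, and the number of calls on single libraries. At equal covered length 74 promoters rose and 214 fell, and on the log2 scale 244 rose and 106 fell. Without HC replicate 2 there were 19 and 15, and without HC replicate 3 there were 0 calls with 302 higher and 240 lower at an unadjusted p under 0.05. Without PC replicate 2, 6 and 8 there were 326, 217 and 263 rises and 111, 65 and 146 falls. The 9 other splits of the 5 libraries each gave 0 limma calls. On chromosome X, H3K27me3 covered 11 ± 6.19 Mb in PC and 30.3 ± 6.47 Mb in HC (exact permutation p = 0.1, the smallest possible, adjusted p = 0.6). On the autosomes it covered 63.8 ± 9.47 Mb and 68.2 ± 7.09 Mb (exact permutation p = 0.6). Among autosomal genes alone 119 rose and 20 fell, and at equal autosomal covered length 83 rose and 37 fell. Regions of H3K27me3 on chromosome Y covered 0.106 to 0.126 Mb in the PC libraries and 0.0208 to 0.0656 Mb in the HC libraries.

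**Figure D3:**
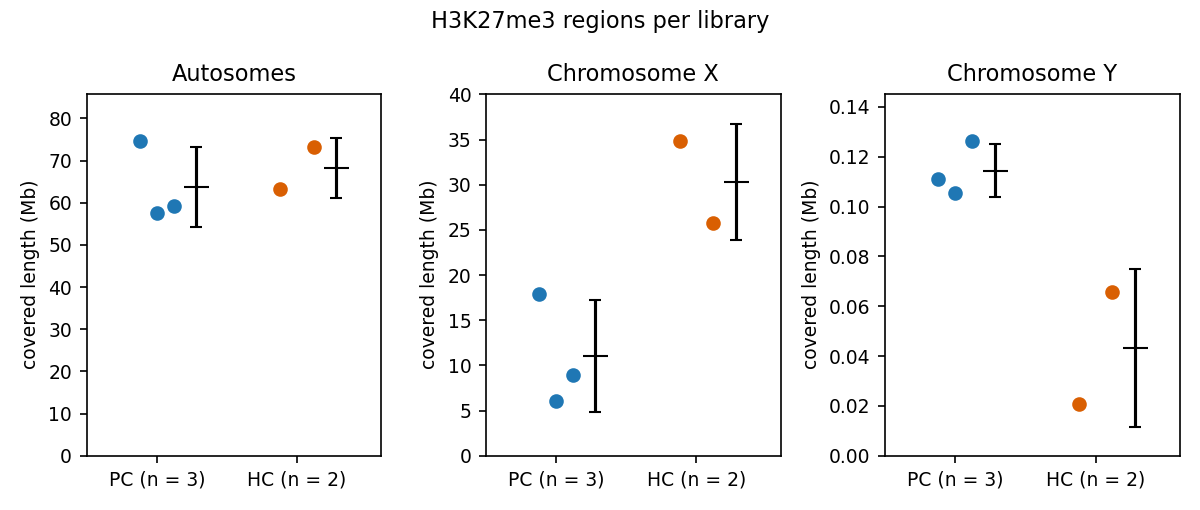
Length covered by H3K27me3 regions in Mb on the autosomes, chromosome X and chromosome Y, with 1 point per library for 3 PC and 2 HC libraries and black bars for mean ± SD. The HC libraries cover 25.7 to 34.9 Mb of chromosome X and the PC libraries 6.06 to 17.9 Mb.

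Genes marked in every library of 1 cell type and in none of the other numbered 37 PC-only and 24 HC-only for H3K4me3, 113 and 61 for H3K9ac, and 181 and 79 for H3K27ac. They numbered 110 and 254 for H3K27me3, 194 and 90 for H3K36me3, and 88 and 46 for H3K9me3. The highest counts from the 9 other splits were 134 and 92, 101 and 170, 125 and 128, 130 and 105, 92 and 210, and 79 and 114, in the same order of marks. For every mark but H3K27me3 the HC-only count thus did not exceed what an arbitrary split can give. The same held for the PC-only counts of H3K4me3 and H3K27me3. At equal covered length the PC-only and HC-only counts were 14 and 15, 20 and 112, 31 and 182, 440 and 71, 97 and 226, and 52 and 45. The direction turned for H3K9ac, H3K27ac, H3K27me3 and H3K36me3 and stayed for H3K9me3, while the H3K4me3 counts became nearly equal. At equal autosomal covered length H3K27me3 had 142 PC-only and 126 HC-only autosomal promoters. The greatest differences among PC-only genes were at Kctd4, Chadl, Zfp648, Snap25 and Ifitm5 for H3K4me3, with Kctd4 at 52.9% ± 29.3 in PC and 2.29% ± 3.24 in HC. For H3K9ac they were at Runx2, Col9a1, Uncx, Npas3 and Lmcd1, with Uncx, a homeobox gene of the axial skeleton, at 60% ± 15.6 and 0%. For H3K36me3, Supt4b, Eno1b, Cxcr1, Ccn2 and Prr30 were PC-only, and Ccn2, a matrix-associated growth factor of cartilage, had 88.5% ± 9.95 and 0%. Prm1, Myd88, Cited2, Pcdhb21 and Capza3 were HC-only, and Cited2, a transcriptional co-regulator, had 0% and 84.2% ± 22.3. Prm1 was among the loci treated as transgene loci and left out in an alternative. Its window of 10 kb was HC-only for H3K4me3, H3K36me3 and H3K9me3. Among HC-only genes for H3K27ac were Col2a1, Cdh15, Dpt, Tnxb and Zc2hc1b, with Cdh15, the cadherin of muscle cells, at 0% and 50.3% ± 14.6. For H3K4me3 the HC-only gene Trim29 rose from 0% to 45.4% ± 3.54 (limma adjusted p = 0.0211). It was called with Col2a1 alone of 14259 genes, with 151 higher and 183 lower at an unadjusted p under 0.05, and at equal covered length neither was. Of the 9 other splits, PC replicate 7 with HC replicate 5 gave 344 H3K4me3 calls, PC replicate 1 with PC replicate 2 gave 2, and the rest gave 0, so these 2 calls do not exceed what an arbitrary split can give. Leaving out 1 library gave 5 to 34 H3K4me3 genes higher and 8 to 32 lower, with 34 without PC replicate 2 and 32 without PC replicate 7. H3K9ac gave 1 call, Col2a1, of 13655 (unadjusted 252 higher, 516 lower). This call was lost at equal covered length, with a replicate block and without PC replicate 2, PC replicate 3, HC replicate 2 or HC replicate 3, each of which left 0 genes higher. H3K36me3 gave 0 of 13567 (unadjusted 379 and 483) and H3K9me3 0 of 10477 (unadjusted 99 and 594). On the log2 scale 23 H3K9me3 genes rose and 80 fell, and at equal autosomal covered length 46 H3K36me3 genes rose and 4 fell.

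**Figure D4:**
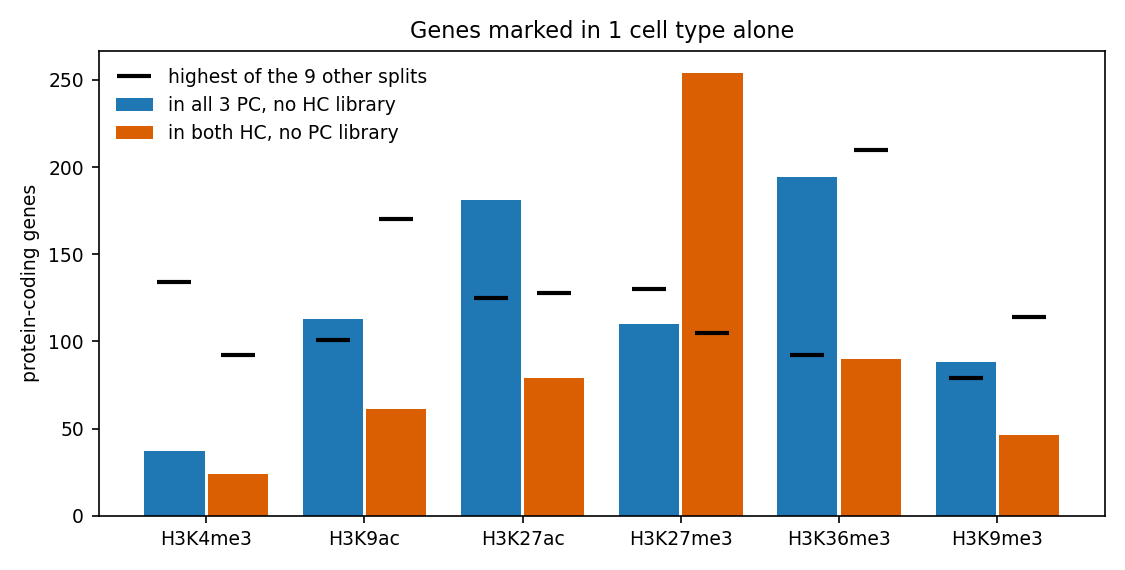
Number of protein-coding genes PC-only (blue bars) and HC-only (orange bars) for each of the 6 marks, with a black line at the highest count of the 9 other splits of 3 and 2 libraries. H3K27me3 has 254 HC-only genes, above the 105 of the highest other split.

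Hox genes, which pattern the body axis and limbs, carried less active chromatin in HC at several members. Hoxb5 fell from 93.9% ± 0 to 30.3% ± 12.8 for H3K9ac and from 73.3% ± 6.88 to 0% for H3K36me3, and Hoxb6 from 95.1% ± 2.42 to 35.4% ± 6.80 for H3K9ac. Adjusted over the list alone, 9 of 37 members fell for H3K9ac, 6 of 21 for H3K36me3, 5 of 38 for H3K27ac and 2 of 38 for H3K4me3, against 0 over all genes for each, and Hoxd12 rose for H3K27ac, a call lost at equal covered length and without PC replicate 3 or PC replicate 8. In the same HC libraries 8 of 14 epidermis and 4 of 10 muscle members rose for H3K9ac, and 5 of 15 epidermis members for H3K27ac, adjusted over their lists alone. Hoxa4 rose for H3K27me3 from 0% to 93.4% ± 9.39 (limma adjusted p = 0.0115 over all genes), a call lost without either HC replicate. For H3K9me3, Hoxa2, Hoxb7 and Hoxc6 of 31 rose adjusted over the list alone, against 0 over all genes, with Hoxb7 at 4.12% ± 7.13 and 91.2% ± 12.4. For H3K36me3, 5 of 19 members were PC-only, among them Hoxb2, Hoxb3 and Hoxb5 (Fisher's exact adjusted p = 0.00111), and at equal covered length 1 was (adjusted p = 0.842). No Hox member was PC-only for H3K9ac (0 of 37), H3K27ac (0 of 39) or H3K4me3 (0 of 39; adjusted p = 1 each). Among Hox genes at equal covered length 5 fell for H3K9ac, 3 for H3K27ac and 1 for H3K4me3, and 1 rose and 0 fell for H3K36me3. The H3K9ac count was 3 without PC replicate 1 or PC replicate 2 and 4 without HC replicate 2 or HC replicate 3, and the H3K36me3 count was 1 without HC replicate 5 or HC replicate 7. The H3K27ac count was 0 without PC replicate 3, 2 without PC replicate 8 and 11 without HC replicate 5, and the H3K4me3 count was 0 without PC replicate 2 or HC replicate 5, 20 without PC replicate 7 and 9 without HC replicate 2. The H3K9me3 count was 1 without HC replicate 5 and 0 without any other library.

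Promoters with H3K4me3 and H3K27me3 together, often called bivalent, numbered 3150 in PC and 3604 in HC, with 2874 in both. A mark counted for a cell type only when present in all its libraries, 3 in PC and 2 in HC, which by itself lowers the PC count of both marks. By this rule 621 promoters counted as H3K4me3 only in PC and as both marks in HC, and 222 the reverse. H3K27me3 was absent from every PC library at only 184 of the 621, and from both HC libraries at 90 of the 222. The others carried it in a part of those libraries. On the cartilage list 11 members had both marks in PC and 16 in HC, and 17 and 10 had H3K4me3 alone. On the hypertrophic list both marks were at 9 and 12 members, and on the Hox list at 37 and 39. Requiring a mark in only 2 libraries of each cell type loosens the rule in PC alone. The counts of 621 and 222 then became 361 and 525. At equal covered length they were 134 and 405, so the direction turned. Without H3K27me3 HC replicate 2 they were 1072 and 127, and without H3K27me3 PC replicate 8 they were 479 and 376.

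Distal H3K27ac regions, which include enhancers, differed near cartilage genes. Of PC-only distal regions, 34 had a cartilage list member as nearest gene, against 0 HC-only regions (Fisher's exact adjusted p = 5.61e-05). They lay near Sox6 (10 regions), Sox5 (4), Acan (4), Sox9 (3), Col9a1 (3) and Hapln1 (3), among others. The test counted regions near the same gene as separate although they may change together. The Fisher p-values of distal regions thus describe regions, not genes, and may overstate the evidence. Near hypertrophic genes there were 24 PC-only and 9 HC-only regions (adjusted p = 0.93), and 8 of the HC-only ones were next to Col10a1, the gene in the transgene of the HC strain. Near epidermis genes there were 1 and 6 (adjusted p = 0.0698). Of 138627 distal regions 2972 were PC-only and 1458 HC-only, against 1786 and 4213 in the highest other splits. After trimming to equal covered length 590 were PC-only and 1116 HC-only. PC-only regions numbered 4927, 7185 and 5272 without PC replicate 3, 5 and 8 and 6875 without HC replicate 7, and HC-only regions 20696 and 10572 without HC replicate 5 and 7. The HC-only share near cartilage genes was then 38.6% and 19.4%, still below that of other genes (Fisher's exact adjusted p = 3.43e-15 and 1.82e-10).

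Some promoters of muscle and endothelial genes carried H3K9ac in HC libraries alone. Among muscle genes these were Pax7, the regulator of muscle stem cells (0% to 51.8% ± 0), Des, which encodes desmin (0% to 22.5% ± 10.6), and Cdh15 (0% to 20% ± 0), 3 of 9 members (Fisher's exact adjusted p = 0.00111). Among endothelial genes they were Pecam1 (0% and 10% ± 7.07), Esam (0.733% ± 1.27 and 11.1% ± 1.56) and Egfl7 (0% and 13.2% ± 6.03), 3 of 10 members (adjusted p = 0.00111), while Plvap, also of endothelium, was PC-only. Each list had 1 such member at equal covered length (adjusted p = 0.372 and 0.329). For H3K9ac 11781 genes were marked in all 5 libraries and could not be HC-only. Lists of weakly marked promoters can thus pass this test without a difference between the cell types. The 61 HC-only H3K9ac genes were also fewer than the 170 of the highest other split. Adjusted over the list alone, 4 of 10 muscle members rose for H3K9ac and Tnnt3 fell, against 0 over all genes, and without HC replicate 2 none and without HC replicate 3 1 rose. Of 4 muscle members tested at equal covered length 1 rose and 1 fell. For epidermis 8 of 14 members rose for H3K9ac adjusted over the list alone, against 0 over all genes, and 2, Grhl3 and Cldn4, were HC-only (Fisher's exact adjusted p = 0.0566), with Perp, a protein of cell junctions, at 10% ± 13.2 and 50% ± 0 and Cldn4, a claudin, at 0% and 22.4% ± 7.30. The epidermis count was 5 at equal covered length and without PC replicate 3, 2 without HC replicate 2 and 4 without HC replicate 3. The 5 epidermis members higher for H3K27ac became 0 at equal covered length or without PC replicate 5. Of 10 endothelial members 0 passed limma for H3K9ac, with 3 higher and 0 lower at an unadjusted p under 0.05. Across the 3 active marks the muscle list had 0 PC-only and 5 HC-only calls, endothelium 1 and 5, epidermis 0 and 4, perichondrium 0 and 2, blood 0 and 1, osteoclast 2 and 0 and neural 2 and 0, against 331 and 164 for all genes.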

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

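The alternatives with both gene ends, without single-bin regions, without the transgene loci, on autosomal genes only and at equal autosomal covered length were chosen after seeing the data, as were the cartilage counts adjusted over the list alone. Of 825 recomputed values, 421 of the values that answer a comparison stayed within the limits set, 179 moved, 9 reversed and 10 lost their call, and of the values of single genes 156 kept their side of the threshold and 50 lost it. For a difference in region number, covered length or Jaccard index the limit was its sign alone, and for a count 1.5 times its value. The cause of the changes was not tested, except that leaving out a library loosens the rule of presence in every library of 1 cell type and so raises its counts. Region lists without scores could not be made stricter except by width, and the unknown read depth limits every comparison of list length. Leaving out an HC library leaves 1, which limma assumes to vary like the others.

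At equal covered length the PC-only and HC-only genes were 14 and 15 for H3K4me3, 20 and 112 for H3K9ac, 31 and 182 for H3K27ac, 440 and 71 for H3K27me3, and 97 and 226 for H3K36me3, and PC-only H3K9me3 genes were 52. Limma gave 0 higher for H3K4me3 and H3K9ac, 0 lower for H3K27ac, and 74 higher and 214 lower for H3K27me3. The hypertrophic H3K9ac, muscle H3K9ac, endothelium H3K9ac and Hox H3K36me3 lists each had 1 member called (adjusted p = 0.329, 0.372, 0.329 and 0.842). Promoters with both marks were 1612 in PC and 1527 in HC, with 134 that had H3K4me3 only in PC and both marks in HC and 405 the reverse. Distal PC-only H3K27ac regions were 590. On the cartilage list 9 members were lower for H3K27ac and 4 higher for H3K27me3.

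With lists trimmed to equal autosomal covered length, PC-only and HC-only genes were 14 and 13 for H3K4me3, 19 and 104 for H3K9ac, 30 and 183 for H3K27ac, and 95 and 216 for H3K36me3, with 126 HC-only for H3K27me3 and 45 PC-only for H3K9me3. Limma gave 0 higher for H3K4me3 and H3K9ac, 0 lower for H3K27ac, 83 higher for H3K27me3, and 46 higher and 4 lower for H3K36me3. On the cartilage list 9 members were lower for H3K27ac and 4 higher for H3K27me3.

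On the log2(percent + 1) scale limma gave 0 higher for H3K4me3 and H3K9ac, 0 lower for H3K27ac, 106 lower for H3K27me3, and 23 higher and 80 lower for H3K9me3. With all genes covered in any library it gave 0 lower for H3K27ac and 14 lower for H3K27me3. With both gene ends for every gene it gave 0 higher for H3K9ac, 0 lower for H3K27ac and 17 lower for H3K27me3. With regions of a single bin left out it gave 1 lower for H3K27ac, and on autosomal genes only 119 higher for H3K27me3. With at least 1 bp in regions there were 49 HC-only H3K36me3 genes and 1273 PC-only H3K9me3 genes, and with 50% of the gene body required 42 PC-only H3K9me3 genes. With overlap of at least 50% of either region the overlapping share of the group lists was 59.2% of PC and 68.0% of HC for H3K27ac, 62.0% and 74.4% for H3K36me3, and 43.5% of PC for H3K9me3. With a mark required in at least 2 libraries of each cell type, the rule was looser in PC alone. Then 361 promoters had H3K4me3 only in PC and both marks in HC and 525 the reverse. With a replicate block for H3K9ac, pairing libraries of the same number, limma gave 0 higher over all genes and 3 lower on the cartilage list, where correlations of the libraries after removal of group means were -0.0200 and 0.0685 for same-number pairs. No paired analysis was possible for the other marks because PC and HC shared fewer than 2 replicate numbers.

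With 1 library left out at a time, the HC minus PC difference ranged from -38.8 to 6.87 Mb in H3K27ac covered length, from -4146 to 926 in H3K27me3 region number and from -89.9 to 19.3 Mb in H3K9me3 covered length. It was positive without HC replicate 5 for H3K27ac and H3K9me3, and without HC replicate 2 or, at 438.5, PC replicate 2 for H3K27me3. The Jaccard index within minus between ranged from -0.0514 to 0.0466 for H3K4me3, -0.0320 to 0.0415 for H3K9ac, -0.0160 to 0.0872 for H3K36me3 and -0.00783 to 0.0253 for H3K9me3. With 1 PC library left out, the overlapping share of PC and of HC group lists ranged from 75.8% to 90.02% and 91.8% to 97.5% for H3K4me3, 65.8% to 78.6% and 84.7% to 90.01% for H3K9ac, and 41.2% to 47.0% and 70.3% to 74.0% for H3K27ac. It ranged from 67.5% to 70.7% and 57.3% to 62.4% for H3K27me3, 57.3% to 68.7% and 77% to 82.6% for H3K36me3, and 36.2% to 39.3% and 46.2% to 52.3% for H3K9me3. PC-only and HC-only genes ranged from 41 to 146 and 26 to 136 for H3K4me3, 144 to 295 and 74 to 188 for H3K9ac, 220 to 692 and 109 to 327 for H3K27ac, 159 to 234 and 322 to 666 for H3K27me3, 218 to 468 and 117 to 243 for H3K36me3, and 174 to 190 and 60 to 321 for H3K9me3.

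With 1 library left out limma gave 5 to 34 higher and 8 to 32 lower for H3K4me3, 0 to 1 higher and 0 to 1 lower for H3K9ac, 0 to 2 lower for H3K27ac, and 0 to 326 higher and 0 to 146 lower for H3K27me3, the 0 without HC replicate 3. The hypertrophic list had 3 to 5 PC-only H3K9ac members (adjusted p = 0.0467 to 0.00118) and the cartilage list 4 to 11 PC-only H3K36me3 members (adjusted p = 0.2 to 5.5e-07). From 479 to 1072 promoters had H3K4me3 only in PC and both marks in HC and 127 to 376 the reverse. Distal H3K27ac regions were 3365 to 7185 PC-only and 1625 to 20696 HC-only. On the cartilage list, adjusted over the list alone, 3 to 13 members were lower for H3K9ac, 4 to 14 lower for H3K36me3 and 0 to 7 higher for H3K27me3.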

Other observations

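All 5 tests of explanations in this part were chosen after the result was seen. Some promoters of signalling genes and of genes of neighbouring tissues gained H3K27me3 in HC, although no Fisher test of HC-only members passed for these lists (adjusted p = 0.303 for perichondrium, 0.408 for Hedgehog, 0.0566 for osteoblast and 1 for Wnt and BMP). Adjusted over the list alone, 6 of 12 members of the perichondrium, tendon and joint list rose, against 5 over all genes. Among them were Scx, a transcription factor of tendon (0% to 39.6% ± 0), Twist1, which restrains osteoblasts (5.58% ± 9.66 to 100% ± 0), and the X-linked tendon gene Tnmd (1.73% ± 2.99 to 100% ± 0). On the Wnt list Nkd1, Rspo3, Wif1 and Wnt5b rose, 4 of 19 adjusted over the list alone and over all genes, with Wif1, an inhibitor of Wnt, at 0% and 40.1% ± 0. On the Hedgehog and PTHrP list Ptch1 and Gli1, targets of Hedgehog, were the 2 of 6 that rose on both scales, and on the BMP and TGF-beta list Bmp7 and Chrd were the 2 of 11. On the osteoblast and osteocyte list Cdh11, Sp7 and the X-linked Phex were the 3 of 5. Ptch1 and Sp7 are also on the hypertrophic list, so their rises were counted there too. For H3K27ac, 2 perichondrium, 2 Wnt, 2 Hedgehog and 3 BMP members fell adjusted over the list alone, against 0 over all genes. Among them were Wnt4 (56.7% ± 12.6 to 5.00% ± 7.07) and Scx (83.6% ± 5.77 to 25.9% ± 30.3). The 2 Hedgehog members, Ptch1 and Pth1r, were also among the hypertrophic members that fell. In the other direction Col3a1, a fibrillar collagen, rose for H3K27ac from 60.1% ± 7.64 to 92.5% ± 10.6 adjusted over the list alone, a call lost at equal covered length and without PC replicate 3 or PC replicate 5, and Tnmd and Dpt were HC-only for H3K27ac. At equal covered length the H3K27me3 counts were 3, 1, 1, 2 and 2 in the order perichondrium (with 1 that fell), Wnt, Hedgehog, BMP and osteoblast, and the H3K27ac counts 1, 0, 0 and 0. The H3K27me3 counts were 2, 1, 1, 0 and 0 without HC replicate 2 and 2, 2, 1, 2 and 0 without HC replicate 3, where 1 perichondrium, 1 Wnt, 3 BMP and 1 osteoblast members fell. The Hedgehog count was 4 without any 1 of the PC libraries and the Wnt count 2 without PC replicate 2. The H3K27ac counts were 0, 3, 2 and 0 without PC replicate 3, 0, 2, 2 and 0 without PC replicate 5, 1, 2, 2 and 0 without HC replicate 5, and 6, 8, 0 and 2 without HC replicate 7.

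The cell cycle list and several lists of other lineages gave few limma calls, which says little about how many genes differ, whereas epidermis gave 17 higher and 1 lower of 76 tests and muscle 6 and 2 of 60. Summed over the 6 marks and adjusted over the list alone, limma called 2 of 144 tests on the cell cycle list, E2f2 for H3K27ac and Ccnd2 for H3K27me3, and both were lost with any 1 library left out. The cyclin-dependent kinase inhibitors gave 0 of 31, with 2 higher and 0 lower at an unadjusted p under 0.05. At equal covered length 1 of them fell for H3K27me3. Leaving out 1 PC library gave single calls for H3K4me3, H3K9ac, H3K36me3 and H3K9me3. Hypoxia and glycolysis genes gave 0 of 87 (unadjusted 3 and 5), with Hif1a, the oxygen-sensitive factor, HC-only for H3K4me3. The other-lineage transcription factors gave 0 of 108 (unadjusted 3 and 6), and 27 of 33 had both H3K4me3 and H3K27me3 in PC and 29 in HC. Housekeeping genes gave 1 of 86, the X-linked Pgk1 for H3K27me3, which was called only with all libraries or without PC replicate 8. Blood genes gave 1 higher and 1 lower of 46, osteoclast genes 1 and 0 of 34 and neural genes 1 and 4 of 64, where Sox10, of the neural crest, fell for H3K4me3 and H3K27ac. Endothelial genes gave 1 and 0 of 61, Ets1 for H3K27me3, which was lost with any 1 library left out. The osteoclast call, Nfatc1 for H3K27me3, was lost without either HC replicate. Zinc finger genes gave 1 of 1572, Zfp648, which fell for H3K4me3 (limma adjusted p = 0.0816 over all genes). For H3K27me3, 2 zinc finger genes rose when adjusted over all genes, against 0 over the list alone. The histone list, chosen by gene name and so holding histone variants too, gave 4 higher and 1 lower of 202, the 4 being X-linked variants of the H2al1 group for H3K27me3, and 1 of them passed without either HC replicate and 2 without PC replicate 2 or PC replicate 8. At equal covered length the blood, endothelial, zinc finger and histone calls named here were lost and 1 neural call, for H3K4me3, was left, while other calls appeared, 2 higher and 3 lower for zinc finger H3K27me3, 1 and 1 for blood H3K27me3 and 1 higher for osteoclast H3K4me3. For H3K9me3, 10 of 381 olfactory receptor genes rose and 5 fell, against 0 over all genes, with Olfr714 at 0% and 100% ± 0. The counts were 12 and 3 at equal covered length, 0 and 0 without PC replicate 3 or HC replicate 5, 1 and 8 without HC replicate 2 and 10 and 17 without PC replicate 6.

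Col2a1 and Col10a1, which drive Cre in the PC and HC strains, stood apart from their lists. For Col2a1 a candidate explanation is extra copies of its sequence in the transgene of the PC strain, which would put edges at shared positions, and 6 of 6 PC libraries of H3K27me3 and H3K9me3 share the start of the promoter region. Of the HC libraries only the 2 of H3K27me3 have a region there, and neither shares the start. In the whole genome 9 positions share the start of a region of at least 4000 bp in all 6 lists. For Col10a1, extra copies in the HC strain may add regions. Of the 9 windows of 10 kb that were HC-only in at least 3 marks, 6 lay within 100 kb of it, against 0 of 69 windows that were PC-only. This count restates the pattern that prompted it, and a change of Col10a1 in the cells could give the same, so it cannot decide. At Col2a1 the active-mark regions of 9 of 9 PC libraries ended at 98001200. The H3K36me3 regions of PC replicates 4, 5 and 6 ended at 98000800. In HC, the H3K4me3 region of replicate 5 started at 98001201. Shared PC edges across all 6 marks argue against cell type or age as the only cause at the Col2a1 promoter. For Col10a1, cell type and age differ between the same libraries and stay open. The values of both genes may describe the transgenes as well as the cells.

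More promoters were HC-only than PC-only for H3K27me3, on chromosome X (57 HC-only, 3 PC-only) and on the autosomes (197 and 107). Marked promoters per library numbered 4684 ± 192 in PC and 4932 ± 341 in HC, with overlapping spreads. On chromosome X fewer male embryos behind the HC libraries could account for the excess of HC-only promoters. The highest Y covered length of an HC H3K27me3 library was 0.0656 Mb, under the lowest PC value of 0.106 Mb. In other marks the groups overlapped, with 0.242 and 0.313 Mb of Y in HC against 0.088 to 0.299 Mb in PC for H3K36me3. Those HC libraries were replicates 5 and 7, against 2 and 3 for H3K27me3, and the labels do not link equal numbers. H3K9me3 HC replicate 2 covered 0.526 Mb, within the PC range of 0.164 to 0.625 Mb. For H3K4me3 HC covered 0.0034 and 0.0086 Mb and PC 0.0038 to 0.171 Mb. For H3K9ac HC covered 0.0042 and 0.0046 Mb and PC 0.0002 to 0.206 Mb. For H3K27ac HC covered 0.0008 and 0.0248 Mb and PC 0.0106 to 0.0172 Mb. Embryo sex thus cannot be told apart from a difference between the cells, and on the autosomes it was not tested. Longer HC lists cannot be told apart from such a difference on the autosomes either, because at equal autosomal covered length 126 promoters were HC-only and 142 PC-only but limma called 83 higher and 37 lower. The age of the embryos stays open and was not tested.

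Some muscle, endothelium and epidermis promoters carried H3K9ac in HC libraries alone (3 of 9, 3 of 10 and 2 of 14), and cells of other types among the sorted HC cells are a candidate explanation, although the YFP gate of the sort would remove cells without the reporter. Of these promoters 5 had H3K27me3 in every PC library and 5 of 5 kept it in both HC libraries, but so did 33 of 33 others, so the measure was saturated and other cells cannot be told apart from a change in the HC. Another 11 abundant genes of muscle, skin, blood and vessels, among them Acta1, Ttn, Krt14 and Hba-a1, were picked after the result was seen. Of these, 0 had H3K9ac or H3K4me3 and 1, Cdh5, had H3K27ac in both HC libraries. In 1 HC library, H3K4me3 was at Acta1, Krt5 and Krt14 and H3K27ac at Actc1 and Ttn. These picked genes cannot decide the question. No gene of these 3 lists is on another list. H3K27ac was in all 3 PC libraries at 4 of 20 muscle, 3 of 18 endothelium and 9 of 18 epidermis members. It was in both HC libraries at 11, 5 and 12 members, where only 2 libraries had to carry it. Cells of other types could also lower the active marks of cartilage and hypertrophic genes in HC, which was not tested.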
